A study of Mus musculus with 6 samples.

How the data were processed

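Gene expression was measured on 6 Affymetrix-type arrays, each hybridised with RNA from mouse regulatory T cells (Treg), the CD4 T cells that carry the transcription factor Foxp3 and restrain immune responses. The cells had been sorted as CD4+YFP+ from mice of C57BL/6 background, per the labels. Per the labels' protocols, 100 ng of total RNA per sample was amplified with the MessageAmp Premier kit and labelled with biotin. The 3 control arrays carry B6_WT titles and a Foxp3cre genotype. The other 3 arrays carry USP7 titles, and the series text describes a Usp7 conditional knockout made with Foxp3cre, whereas their genotype field names a floxed HDAC11 allele. This conflict between labels was left as it stands: groups were taken from the titles, the groups are called control and USP7-titled, and both Usp7 and Hdac11 were examined in every array. The series text speaks of independent samples but does not say whether each came from its own animal, so p-values measure the spread between these samples.

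The values are log2 expression per probe set as the authors deposited them, with no background, detection call or scanner file analysed here. The base of the logarithm was read from the values, which ran from 2.21 to 14.47 over the gene probe sets. The summarisation and normalization steps are not given in the sources used here. The sorted values of each array lay within 0.0916 of the mean distribution, and array medians ran from 7.91 to 7.96. No further normalization was applied. Forced similarity of the arrays can hide a change in total RNA per cell, and fold changes at low signal are compressed by background.

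Of 22690 probe sets, 64 array controls were set aside. A platform annotation table gave 20380 probe sets a single gene symbol, 691 several symbols and 1555 none. Only those with a single symbol named genes. Of these, 20351 matched the mouse reference gene table (assembly GRCm38.p6) by gene identifier, and 0 symbols needed updating. The sources name no genome build, so coordinates are not given and the reference served only for names and for which genes neighbour each other. For each of 12393 genes the probe set with the highest mean over all 6 arrays was used, a choice blind to the groups.

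USP7-titled and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Changes are USP7-titled minus control on the log2 scale with standard errors (SE). The probe sets of Usp7 and Hdac11 were tested in a fit over all gene probe sets and also by a two-sided exact permutation test, whose smallest possible p with 3 against 3 arrays is 0.1. Shifts of 30 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists. Camera with an estimated correlation and the rotation test fry were alternatives. Array precision is limited by their number, 3 per group; the median residual SD per gene was 0.136.

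The test, the gene lists and the rule for named genes were fixed in advance. Usp7, Hdac11 and Foxp3 are always named. The rule then took 12 rises and 12 falls, the largest among genes past the threshold whose groups did not overlap and whose higher group mean exceeded the median gene, leaving out predicted and clone names. From each list it took up to 4 members past the threshold with the largest change, or 2 with the smallest p where none passed, and from each marker list also the 2 members with the highest mean. This gave 131 genes. Of these, 57 had more than 1 probe set, 7 had a probe set of opposite sign, and in 2 such a probe set passed the threshold. In 16 the brightest passed and another did not, and in 15 another differed from it by more than 1 on the log2 scale. Besides genes whose probe sets are described below, these were Kat2b, Pfkp, Ms4a1, Zbtb46 and Irf8 for the first, and Xist and C1qb for the second. Members outside this rule that are named below were chosen after their values were seen.

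On simulated data for this comparison, with 12393 genes of which 200 were changed, the limma fit recovered 55.2% of changes of 0.5, 98.5% of changes of 1 and 100% of changes of 2 on the log2 scale. It made 13 false calls, 7.14% of its calls. In the data far more genes passed, 4078. The Benjamini-Hochberg adjustment depends on the share of changed genes, so these rates need not hold for the data. Camera called a simulated shift of 0.5 in the glycolysis list and 0 of the unshifted lists; genes in that simulation were independent.

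Alternatives chosen before the data were examined were quantile normalization, centring on array medians, leaving out the 40% of probe sets with the lowest mean, averaging the probe sets of a gene, testing all probe sets, eBayes without trend or robust, array weights, the replicate number as a block, other thresholds, the other set tests, leaving out genes held by several lists, and leaving out each array. Scaling to 18 hybridization spike probe sets and leaving out genes on the X and Y chromosomes were added after seeing the data.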

Results

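Transcripts were profiled in sorted CD4+YFP+ Treg from 3 control and 3 USP7-titled samples, with 1 array each, to ask what loss of Usp7 in Treg does to gene expression. Usp7 is a deubiquitinase, an enzyme that removes ubiquitin from proteins, and its known substrates include Mdm2, p53 and Foxp3. Array medians were 7.91 to 7.96 on the log2 scale. Arrays of a group resembled each other more than those of the other group: across gene probe sets, Pearson's r was 0.9950 to 0.9958 among controls, 0.9917 to 0.9927 among USP7-titled arrays and 0.9703 to 0.9749 between groups. No pair of arrays was identical. The 3' minus 5' difference of the Gapdh control probe sets, a sign of RNA integrity, was 0.989 to 1.23 in controls and 0.908 to 0.986 in USP7-titled arrays; for actin it was -0.286 to -0.151 and -0.180 to -0.155.

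Usp7 transcript was lower in every USP7-titled array. For its brighter probe set the controls read 11.69, 11.73 and 11.61, and the USP7-titled arrays 10.54, 10.70 and 10.76. Its mean went from 11.68 ± 0.06 to 10.67 ± 0.11 (SD, n = 3 each), a log2 change of -1.01 (SE 0.07, 95% interval -1.17 to -0.86), which left 49.6% of the control level (limma adjusted p = 2.04e-06). The other Usp7 probe set changed by -0.98 (SE 0.09) to 50.8% of control (limma adjusted p = 2.41e-05).

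Hdac11, the deacetylase named in the genotype field of the same arrays, was dim in both groups. Its brighter probe set read 6.66, 6.20 and 6.29 in controls and 6.04, 5.65 and 5.74 in USP7-titled arrays, a change of -0.58 (SE 0.16, limma adjusted p = 0.019). Its control mean stood at the 27.7th percentile of all probe sets. Without control replicate 1 the change was -0.44 (limma adjusted p = 0.0878), and without USP7-titled replicate 2 it was -0.50 (limma adjusted p = 0.0645). The dimmer probe set, at the 5.98th percentile, changed by -0.22 (SE 0.17, limma adjusted p = 0.354). The exact permutation p was 0.1, the smallest possible, for both Usp7 probe sets and the brighter Hdac11 probe set, and 0.4 for the dimmer. Where the probes lie relative to any deleted exon was not analysed here, so a remaining signal does not check how complete a deletion was, and these levels do not settle which allele the mice carried.

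Foxp3 fell the furthest of the genes tested after the X-inactivation RNA Xist. It went from 12.98 ± 0.15 in controls to 7.004 ± 0.25 in USP7-titled arrays (SD, n = 3 each), a change of -5.98 (SE 0.13) or 63.1-fold (limma adjusted p = 6.71e-10). A single probe set reports it, and where its probes lie in the gene was not analysed here. A difference between the groups' Foxp3 alleles is taken up below as a candidate explanation. Ccdc22, which lies beside Foxp3 and overlaps it in the reference annotation, fell by 3.06 on the log2 scale, or 8.33-fold.

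**Figure D1:**
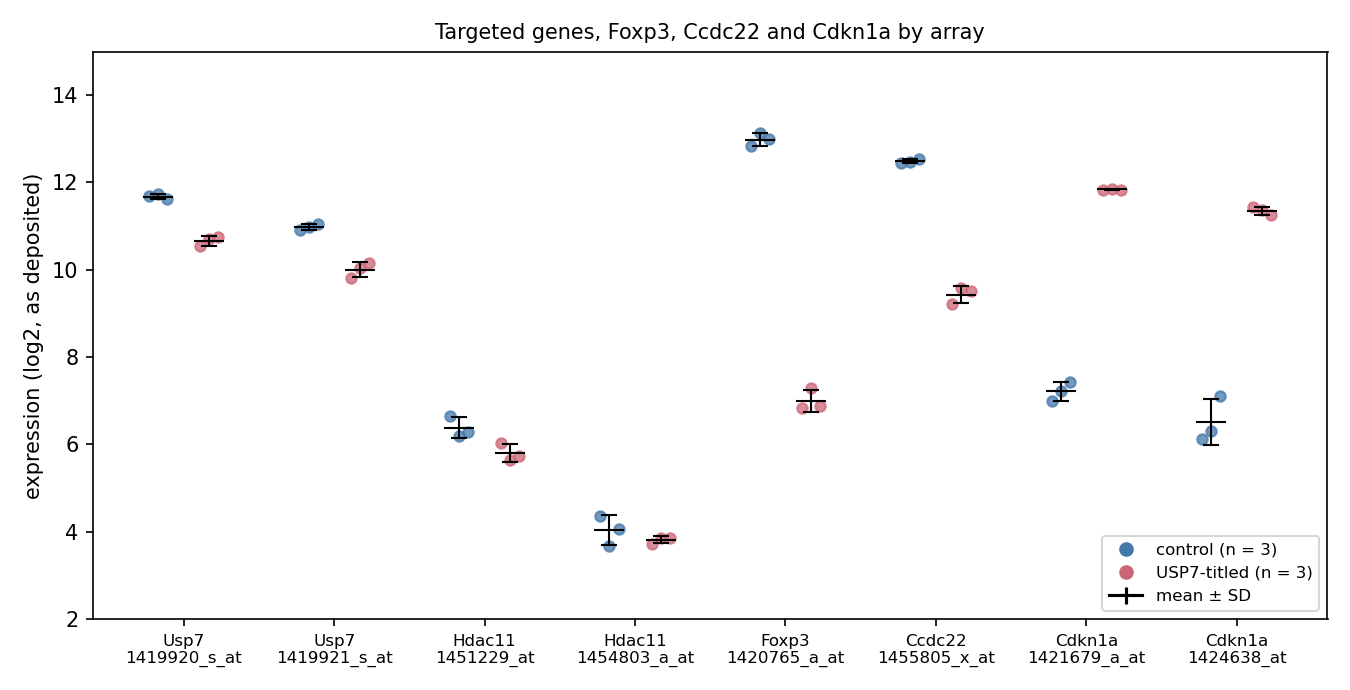
Expression on the log2 scale as deposited (y axis) of each probe set of Usp7, Hdac11, Foxp3, Ccdc22 and Cdkn1a (x axis), with 1 point per array, the 3 control arrays in blue and the 3 USP7-titled arrays in red, and bars for mean ± SD. Usp7 fell to 49.6% and 50.8% of control by its probe sets, Foxp3 went from 12.98 to 7.004, and Cdkn1a rose from 7.22 to 11.84 by its brighter probe set.

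Beyond these genes the groups differed widely. Of 12393 genes, 2102 were higher and 1976 lower in USP7-titled arrays, together 32.9% of genes. Rises were the larger: 387 genes rose and 152 fell by at least 2-fold, and 94 rose and 11 fell by at least 4-fold. In 5650 genes (45.6%) the groups did not overlap, against 10% expected by chance. The balance of rises and falls depends on the scaling. As deposited, 51.5% of changed genes were higher; scaled to the hybridization spikes, 2968 genes were higher and 944 lower, 75.9% higher, with the median of all genes moving from -0.05 to 0.11.

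Largest changes were ranked among genes with groups that did not overlap and a higher group mean above the median gene, which leaves out dimmer genes such as Khdc1a (-3.21) and Gpr34 (-2.66). The rises were led by the Y-linked Eif2s3y (5.65, SE 0.26), the chemokine Ccl8 (5.08, SE 0.12), the cyclin-dependent kinase inhibitor Cdkn1a, known as p21 (4.62, SE 0.11), and Psrc1, a spindle-associated protein (4.35, SE 0.11). Akr1c18 rose by 3.83 and the galectin Lgals3 by 3.50. The other 6 act in the cell cycle: Bub1 (3.71), Birc5 (3.70), Cep55 (3.65), E2f8 (3.51), Ube2c (3.46) and Spag5 (3.45). Dimmer probe sets of some rose less: Psrc1 by 3.34 and 0.894, Bub1 by 1.95, Cep55 by 2.37 and Spag5 by 1.49 and 1.12. The largest falls were Xist (-7.20, SE 0.22), Foxp3, the vesicle traffic GTPase Rab6b (-4.62, SE 0.12), Eps8l1 (-3.30), the lubricin gene Prg4 (-3.19), Ccdc22, the guanylate-binding protein Gbp2b (-2.88), Mapk12 (-2.02), Npy1r (-1.99), Fbxl12 (-1.90), the chemokine receptor Ccr6 (-1.75) and Lrig1 (-1.74). Of these, Npy1r had a dimmer probe set that did not change (0.01). The highest limma adjusted p among these rises and falls was that of Mapk12, 4.65e-05.

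Sex-linked transcripts separated the groups. Xist read 12.50 in controls and 5.30 in USP7-titled arrays, whereas Eif2s3y read 4.50 and 10.15. The Y-linked Kdm5d rose by 2.58 and Uty by 1.69 or more by each of their probe sets. All 3 control arrays thus had the female pattern and all 3 USP7-titled arrays the male pattern, so sex and group cannot be told apart in any comparison here. With genes on X and Y left out, 2039 genes were higher and 1915 lower.

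**Figure D2:**
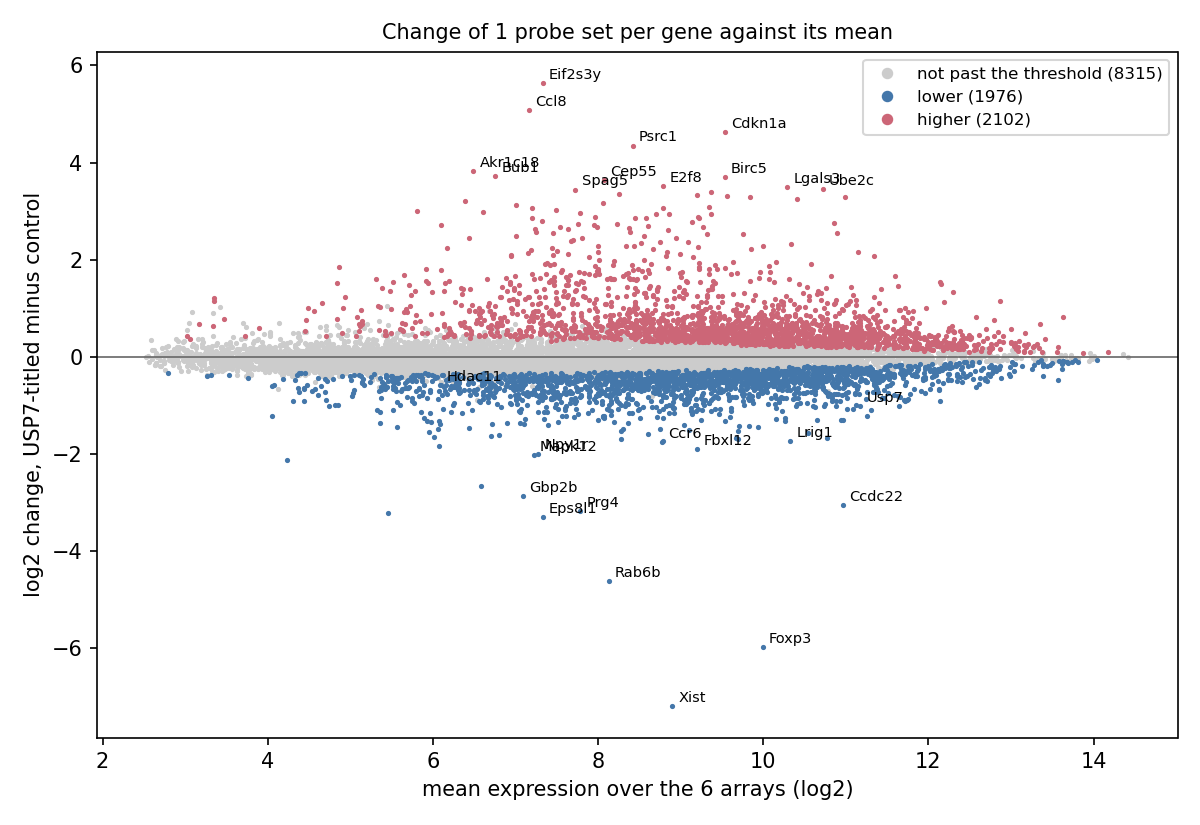
Log2 change, USP7-titled minus control (y axis), against mean log2 expression over the 6 arrays (x axis) for 12393 genes, 1 point per gene, with the 2102 higher genes in red, the 1976 lower genes in blue and the rest in grey. The genes named by the rule as largest rises and falls are labelled, with Foxp3 at -5.98 and Cdkn1a at 4.62.

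Cell cycle genes rose together. All 34 measured members of the G2/M and mitosis list rose, with a median log2 change of 2.65; they include the survivin gene Birc5, the ubiquitin-conjugating enzyme Ube2c, the checkpoint kinase Bub1 and Cdca3 (3.40, with dimmer probe sets at 0.14 and 0.00076). In the replication and G1/S list 30 of 31 members rose and 0 fell, with a median of 1.38. Cdc6, a licensing factor of replication origins, rose by 2.66, the ribonucleotide reductase subunit Rrm2 by 2.56, the DNA methylation cofactor Uhrf1 by 2.32 and Gins1 by 1.98. Camera's adjusted p was 8.71e-36 for G2/M and 1.49e-24 for G1/S, and 0.00904 for each with an estimated correlation.

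Targets of the tumour suppressor p53 rose as a list: 19 of 29 measured members rose, 4 fell and 6 did not pass, with a median of 0.68 (camera adjusted p = 7.05e-08, and adjusted p = 0.0228 with an estimated correlation). Cdkn1a, which halts the cell cycle, rose 24.6-fold, and its other probe set rose by 4.83. Psrc1 rose 20.4-fold by its brightest probe set; the apoptosis-linked Phlda3 rose by 2.85 and Pmaip1, which encodes Noxa, by 2.69. The members that fell were Sesn1 (-1.01), Ddb2 (-0.62), Rrm2b (-0.46) and Btg2 (-0.42), named after their values were seen. Mdm2, the ubiquitin ligase of p53, rose by 0.41. Among apoptosis regulators 8 of 23 rose and 8 fell (camera adjusted p = 0.81). Pmaip1, Apaf1 (1.41) and Bak1 (0.96), which promote cell death, rose, while the survival gene Bcl2 fell by 0.92. The median of that list was -0.14 and its mean 0.12. In the same arrays the sex-linked transcripts and the myeloid markers described below also differed.

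Most Treg signature genes changed far less than Foxp3. Of 33 measured members 7 rose, 17 fell and 9 did not pass, with a median of -0.12 (camera adjusted p = 0.0141, and adjusted p = 0.0961 with an estimated correlation). Gpr34 fell by 2.66, the ectoenzyme Nt5e, known as CD73, by 1.44 and the suppressive mediator Fgl2 by 1.21. Of other members, picked after their values were seen, Ctla4 fell by 0.36, Ikzf2 by 0.21, Il2ra by 0.17 and Tnfrsf18 by 0.12. These do not stand for the list, in which Itgae, for example, fell further (-0.83). Without genes on X and Y the list's camera adjusted p was 0.0872. The list of targets and partners, drawn up mainly around Usp7, had 3 of 18 members higher and 8 lower. Its median was -0.27 (camera adjusted p = 0.0388, and adjusted p = 0.22 with an estimated correlation). The list holds Usp7, Hdac11 and Foxp3 themselves, so its fall is in part that of genes the labels name. Of its members Uhrf1 rose, while Foxp3, Usp7 and the related deubiquitinase Usp11 (-1.37) fell. Without genes on X and Y the list's camera adjusted p was 0.297. Of 18 deacetylases and acetyltransferases 2 rose and 9 fell, among them Hdac9 (-0.90), Kat6b (-0.84), Kat2b (-0.68) and Sirt7 (-0.48). The list did not pass (camera adjusted p = 0.0559). Under spike scaling 3 members rose and 4 fell, yet the list passed as lower (camera adjusted p = 0.0481). Its median there was -0.129, against 0.108 for all genes.

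Genes of effector Treg, the activated state found in tissues, rose in 13 of 25 measured members and fell in 2, with a median of 0.32 (camera adjusted p = 1.15e-05, and adjusted p = 0.0254 with an estimated correlation). The cytotoxic protease Gzmb rose by 3.29, the chemokine receptors Cxcr6 and Cxcr3 by 1.61 and 1.27, and the transcriptional regulator Id2 by 1.24, with a dimmer Id2 probe set at -0.10. Genes of naive or resting T cells fell in 15 of 17 members and rose in 0, with a median of -0.50 (camera adjusted p = 4.78e-08, and adjusted p = 0.0228 with an estimated correlation). The IL-7 receptor gene Il7r fell by 1.31, Bach2, a repressor that maintains quiescence, by 1.07, Bcl2 by 0.92 and Tlr1 by 0.91. Scaled to the hybridization spikes, 9 naive or resting members fell and 1 rose, with a median of -0.34. These lists overlap others: 18 of the 25 effector members stand in a further list. Gzmb is also a CD8 T and NK marker. Gzma and Nkg7 of that marker list rose in the same arrays, although the list did not pass, and the myeloid markers rose as a list, as described below. The effector genes therefore need not come from Treg alone.

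Helper T cell cytokines and regulators went both ways, with 9 of 23 higher and 7 lower (camera adjusted p = 0.4). The chemokine Ccl3 rose by 1.91, interferon gamma (Ifng) by 1.60 and Tbx21, the Th1 regulator known as T-bet, by 1.40, while Ccr6 fell. Immediate early and T cell receptor response genes fell in 9 of 23 and rose in 1 (camera adjusted p = 0.00236, and adjusted p = 0.0543 with an estimated correlation): Jun fell by 1.69, Myc by 0.77 and Egr2 by 0.62, and Ier3 rose by 1.08. T cell receptor and lineage genes had 4 of 26 higher and 11 lower (camera adjusted p = 0.0223, and adjusted p = 0.22 with an estimated correlation). Under spike scaling the balance turned, with 7 higher and 6 lower, and the list did not pass (camera adjusted p = 0.408). Runx3 rose by 0.68, and Bcl11b and Tox fell by 0.57 and 0.50. Zap70 rose by 0.48 by its brighter probe set, with the other at -0.41. Migration and adhesion receptors had 9 of 25 higher and 5 lower (camera adjusted p = 0.114), with the integrin Itgae at -0.83 beside Ccr6, Cxcr6 and Cxcr3.

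Energy metabolism and protein turnover genes rose by small amounts. In the oxidative phosphorylation list 30 of 35 members rose and 1 fell, with a median of 0.36 (camera adjusted p = 2.35e-13, and adjusted p = 0.00904 with an estimated correlation). Cytochrome c (Cycs) rose by 0.70, and Atp5g1 and Sdhb by 0.64 each. Uqcrq rose by 0.62 by its brightest probe set only. In the proteasome list 30 of 35 rose and 0 fell, with a median of 0.33 (camera adjusted p = 3.87e-12, and adjusted p = 0.0228 with an estimated correlation). Its examples are Psmd13 (0.63), Psmd6 (0.56), Psmd8 (0.54) and Psma1 (0.65), the last with a dim probe set that fell by 0.98. Glycolysis genes rose in 9 of 20 and fell in 1, with a median of 0.36 (camera adjusted p = 0.000288, and adjusted p = 0.0405 with an estimated correlation): Tpi1 rose by 1.25, Pgk1 by 0.70 and Pfkp by 0.69, while Pdk1, which inhibits pyruvate dehydrogenase, fell by 0.84.

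Cholesterol synthesis genes rose in 11 of 19 and fell in 1, with a median of 0.42 (camera adjusted p = 0.00044, and adjusted p = 0.0405 with an estimated correlation), led by Hsd17b7 (1.54), the sterol carrier Stard4 (1.31), Ebp (0.86) and Fdps (0.79, with a dim probe set at -0.36). In the unfolded protein response list 14 of 26 rose and 2 fell, with a median of 0.17 (camera adjusted p = 0.000288, and adjusted p = 0.0405 with an estimated correlation). Asparagine synthetase (Asns) rose by 1.94, and the endoplasmic reticulum proteins Sdf2l1, Manf and Creld2 by 1.52, 0.85 and 0.83. Heat shock genes had 5 of 16 higher and 1 lower (camera adjusted p = 0.164): Stip1 rose by 0.47, Hspa4l by 0.44 and Hsp90aa1 by 0.38, and Hspb1 fell by 0.47.

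Cytosolic ribosomal protein genes fell in 12 of 28 and rose in 1, with a median of only -0.07 (camera adjusted p = 0.00504, and adjusted p = 0.164 with an estimated correlation). Rpl12 fell by 1.18, Rps25 by 0.57, and the abundant Rps24 and Rps15 by 0.18 each, with a Rps24 probe set at -1.32. Scaled to the hybridization spikes, the list's median was 0.09, still below the all-gene median of 0.11. Its camera direction turned there (camera adjusted p = 0.538). With quantile normalization the ribosomal median was -0.0254, against -0.024 for all genes, with 2 members higher and 7 lower. The list did not pass in that setting (camera adjusted p = 0.106). MYC and ribosome biogenesis genes had 8 of 35 higher and 10 lower (camera adjusted p = 0.521); Myc, Polr1b (-0.62) and Gnl3 (-0.57) fell and Ranbp1 rose by 0.57. Of 37 interferon-stimulated genes 5 rose and 10 fell (camera adjusted p = 0.0854), with falls of Slfn8 (-1.04), Oas1a (-0.99) and Oasl1 (-0.99) and a rise of the dim Ifi204 (1.21).

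Markers of other cell types were examined because a sort can hold other cells. Myeloid markers rose in 18 of 29 measured members and fell in 2, with a median of 0.76 (camera adjusted p = 2.49e-07, and adjusted p = 0.0228 with an estimated correlation). The complement genes C1qb and C1qc, made by macrophages, rose by 2.86 and 2.48, the lysozyme gene Lyz1 by 2.48, with a dimmer probe set at 0.003, and the neutrophil protein S100a8 by 2.07. Of the most abundant members, Ifitm3 rose by 1.60 and the protease Ctss fell by 0.48. In controls 4 of the 29 members lay above the median gene, and 2 of the 29 stand in another list.

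The remaining marker lists did not pass in the main fit. B cell markers had 7 of 18 higher and 1 lower (camera adjusted p = 0.0633, but under the threshold in 6 of 18 other settings, as with quantile normalization at 0.0476), with Ly86 at 1.20, Ms4a1 at 0.998, Pou2af1 at 0.91, H2-Eb1 at 0.91 and the abundant Cd74 at 0.28; the brightest of 11 Ighm probe sets was at -0.04 and others went either way. CD8 T and NK cell markers had 7 of 20 higher and 3 lower, with a median of -0.04 but a mean of 0.51 (camera adjusted p = 0.0971). The cytotoxic genes Gzmb (3.29), Gzma (3.21) and Nkg7 (2.76) and the adaptor Tyrobp (1.85) led it. Dendritic cell markers had 6 of 14 higher and 1 lower (camera adjusted p = 0.143), with Tcf4 (1.005, but 0.05 to 0.13 by 3 of its 6 probe sets), Clec10a (0.98), Bst2 (0.63) and Irf8 (0.37) higher and Zbtb46 (-0.96) lower. Plasma cell markers had 4 of 11 higher and 2 lower (camera adjusted p = 0.201): Creld2, Slpi (0.53) and Xbp1 (0.48) rose, Igha fell by 0.75, and Irf4 was at 0.21 (limma adjusted p = 0.0944).

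Double-positive thymocyte markers had 1 of 13 higher and 2 lower (camera adjusted p = 0.505), Mns1 at 1.31, St6gal1 at -0.76 and Cd1d1 at -0.39, with Tcf12 at 0.02 (limma adjusted p = 0.88). Erythroid and platelet markers had 0 of 14 higher and 1 lower, Gata1 at -0.73 (camera adjusted p = 0.224), with Itgb3 at 0.10 (limma adjusted p = 0.587). Stromal and epithelial markers had 1 of 18 higher, Cdh5 at 0.68, and 2 lower, Pecam1 at -0.66 and Epcam at -0.58 (camera adjusted p = 0.807).

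**Figure D3:**
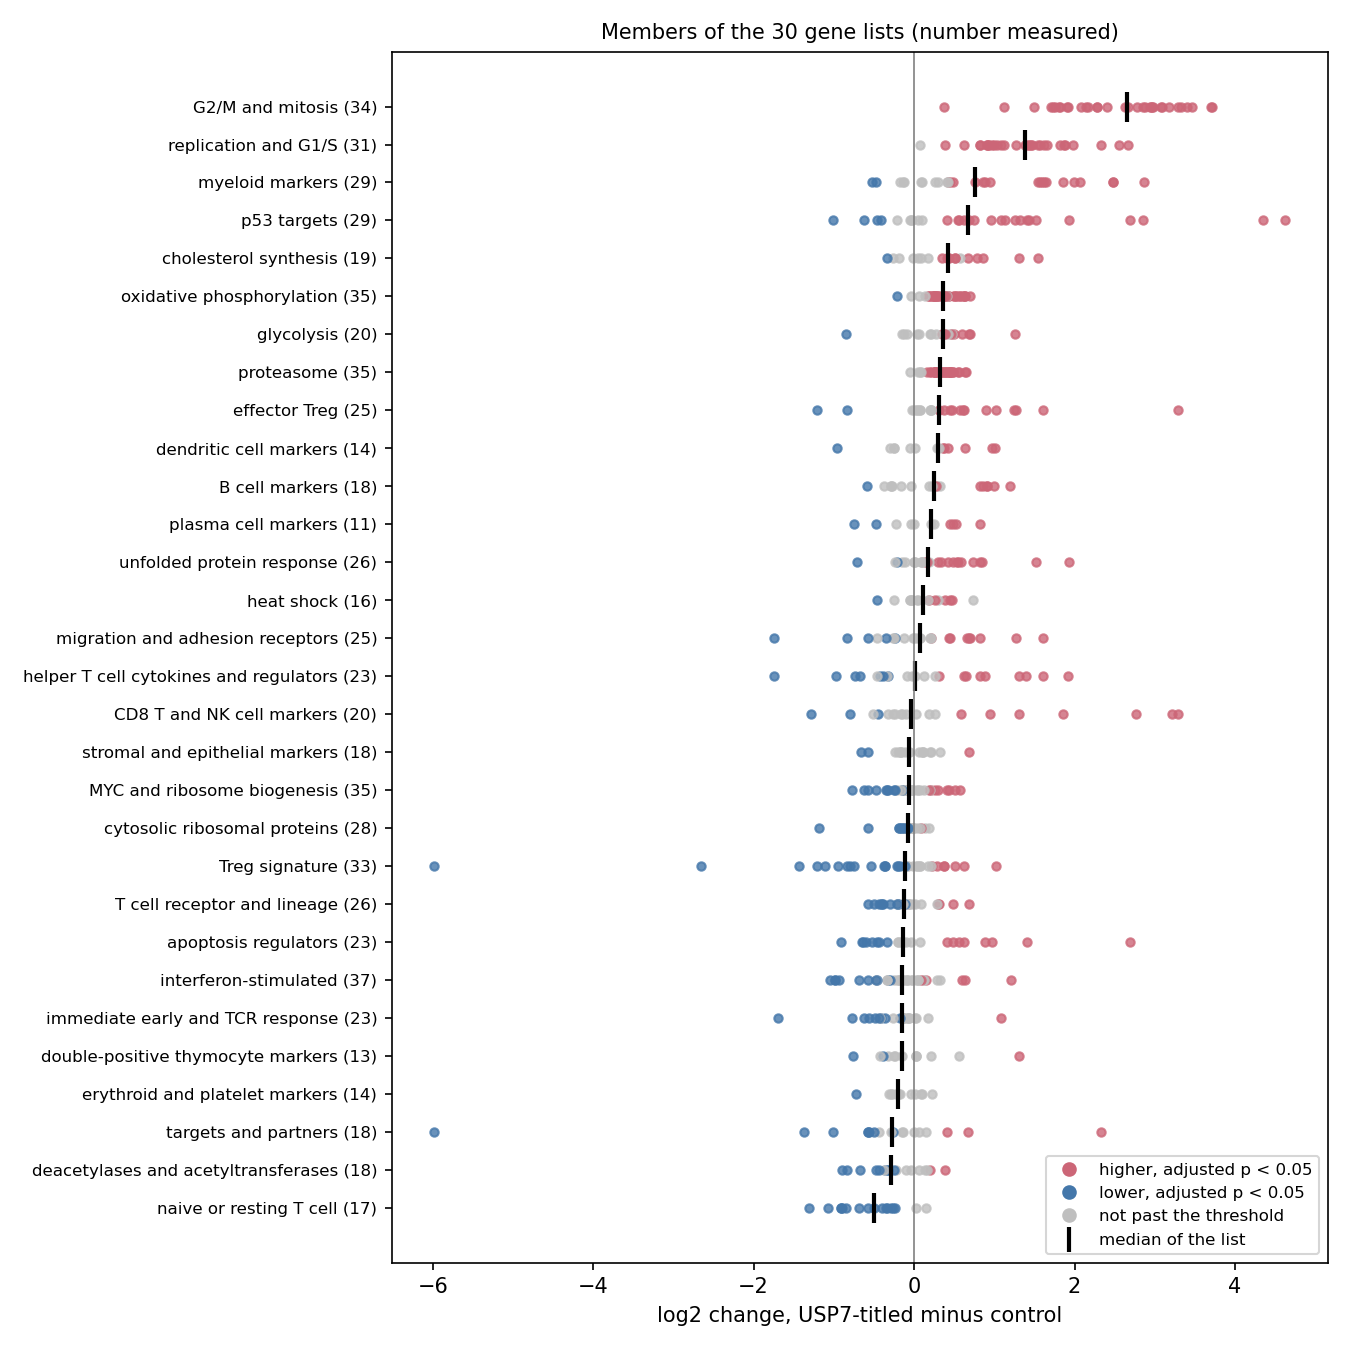
Log2 change, USP7-titled minus control (x axis), of every measured member of the 30 gene lists (y axis, number measured in brackets), with members that rose in red, those that fell in blue and the rest in grey; black ticks are list medians. The G2/M list has the highest median, 2.65, and the naive or resting T cell list the lowest, -0.50.

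Across the 30 lists camera called 10 higher and 6 lower. All these shifts were measured in arrays in which myeloid markers and sex-linked transcripts also differed, so none of them is tied to Treg alone or to Usp7 alone. With an estimated correlation the 10 higher lists and 1 lower list, naive or resting T cells, passed. Adjusted over the list alone, 14 of the 30 lists had the same counts of members, and the largest difference was in the T cell receptor and lineage list, with 5 higher and 14 lower in place of 4 and 11. Scaled to the hybridization spikes, the medians of the Treg signature (0.04), T cell receptor and lineage (0.04) and immediate early (0.01) lists turned positive, near the all-gene median of 0.11. Falls also became fewer there: 13 Treg signature genes fell and 9 rose, 5 immediate early genes fell and 2 rose, and 2 ribosomal protein genes fell and 7 rose. Positive medians were also reached by lists that were not called: interferon-stimulated (0.01, with 7 higher and 8 lower), MYC (0.09, with 10 higher and 2 lower), apoptosis (0.02), CD8 T and NK (0.12), stromal (0.10) and thymocyte (0.004) genes.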

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

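Each group held 3 arrays, so no test for outlying arrays was run, and the single comparison leaves no difference between contrasts to test. Signals above the control arrays appeared in probe sets that the gene comparison does not use. Among probe sets without a gene symbol, 181 were higher and 331 lower in USP7-titled arrays; the largest rise was 5.14 on the log2 scale, from 3.07 to 8.21 (limma adjusted p = 5.38e-09). Among probe sets with several symbols, 164 were higher and 125 lower. The array's control probe set for the middle of Gapdh, which belongs to the glycolysis list, was higher by 0.495 (limma adjusted p = 2.16e-06). Control probe sets named for murine B1 and B2 were lower. B1 changed by -0.535 (limma adjusted p = 4.16e-05), and B2 by -0.255 and -0.35 (limma adjusted p = 0.000277 and 0.0105). Why these differ was not tested.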

How the results depend on the processing

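Spike scaling and leaving out genes on X and Y were chosen after seeing the data; other settings were planned. Testing all probe sets gave 3673 higher and 3865 lower, since more features are tested, and requiring at least 2-fold left 387 and 152. Spike scaling gave 944 lower (2968 higher), because the spikes read 0.159 lower on average in USP7-titled arrays. Single spike probe sets changed by -0.307 to 0.015, so they did not share an offset that would fit all genes. Why they differ was not tested. Spike scaling also left the brighter Hdac11 probe set at -0.4171 (limma adjusted p = 0.0539, with 0.00736 to 0.0878 over its alternatives). Lists called lower numbered 2 without the variance trend and 1 with an estimated correlation, and fry called 18 lists higher; the cause was not tested beyond fry's other question, whether a list moves on balance. Over the planned settings, fry included, the set tests' adjusted p ran from 0.000145 to 0.0961 for the Treg signature, 0.000793 to 0.345 for targets and partners, 1.02e-06 to 0.185 for ribosomal proteins and 0.000997 to 0.22 for the T cell receptor list.

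Uqcrq (-0.06063), Psma1 (-0.1587) and Ighm (0.7446) reversed with probe sets averaged, since their dim probe sets oppose the bright. Apoptosis regulators reversed under fry, where the test called the list higher at a median of -0.1402. Ribosomal proteins reversed in camera direction under spike scaling, though their median of 0.08555 stayed below the all-gene median of 0.108. Why that direction turned was not tested. Medians of 3 other called lists turned positive under spike scaling without a change of camera direction. Of these, the T cell receptor and lineage list lost its call there (camera adjusted p = 0.408). Named genes also lost calls with probe sets averaged (Hdac11, Fdps and Zap70, at limma adjusted p = 0.0583, 0.163 and 0.809), without the trend (Rps24, Rps15 and Ms4a1) and under spike scaling (Polr1b, Rps24, Rps15, Hspb1 and Cd1d1), where Rps24 went to -0.02462 and Rps15 to -0.0235 and Irf4 gained one.

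Leaving out each array in turn gave 1699 to 2095 genes higher, 1435 to 1925 lower, 10 to 11 lists higher and 5 to 7 lower. Usp7 ranged from -1.06 to -0.9497 and from -1.054 to -0.8789 by its probe sets; Hdac11 from -0.6914 to -0.441 and from -0.404 to -0.05594. Of 131 named genes, 6 lost their call without control replicate 1 (Hdac11, Polr1b, Hspb1, Ms4a1, Irf8 and Cd1d1) and 5 without USP7-titled replicate 2 (Hdac11, Hspb1, Ms4a1, Cd74 and Irf8). Without control replicate 2 it was 4 (Polr1b, Hspb1, Pecam1 and Cd1d1), without USP7-titled replicate 3 it was 2 (Irf8 and Cd1d1), and without control replicate 3 or USP7-titled replicate 1 it was Irf8. The targets and partners list lost its call without control replicate 1 (adjusted p = 0.0512) or USP7-titled replicate 3 (adjusted p = 0.0612). Lists that gained a call were deacetylases (0.0438 without control replicate 2, 0.0391 without USP7-titled replicate 2), CD8 T and NK markers (0.0438 without control replicate 2) and B cell markers (0.0375 without USP7-titled replicate 1). Over 18 planned settings, of lists not called in the main fit, deacetylases and B cell markers (lowest adjusted p = 0.00126, all probe sets) passed in 6 each, migration receptors in 4, interferon-stimulated, heat shock and CD8 T and NK genes in 3 each, and 5 others by fry alone.

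Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.0785, -0.0599 and 0.094, and not every array correlated best with its own number. The replicate block gave 2098 genes higher and 1961 lower, and 10 and 6 lists; it changed no call of a named gene, list or targeted probe set. Offsets before the logarithm were not run, as values were log2 already, and filtering or averaging was not applied to single probe sets of Usp7 and Hdac11. No detection calls were used here, so signal over background limits the dimmest genes by an unknown amount.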

Other observations

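Some gene families also moved; 14 families were chosen by symbol after values had been seen, and genes of the fixed lists were left out of them. Genes named as mitochondrial ribosomal proteins rose in 44 of 71 measured members and fell in 2, with a median log2 change of 0.38 (Fisher's exact test for higher calls, adjusted p = 2.07e-17 over both directions of 14 families). Genes with the zinc finger symbol Zfp fell in 62 of 170 and rose in 3, with a median of -0.21 (exact test for lower calls, adjusted p = 4.06e-10). The small nuclear ribonucleoproteins of the spliceosome rose in 5 of 8 and fell in 0 (exact adjusted p = 0.0159). Condensin and cohesin subunits, pooled, rose in 7 of 10 and fell in 2 (exact adjusted p = 0.0012). The large rises were of condensins, such as Ncapg (2.95) and Smc2 (2.11), though the condensin Smc4 fell (-0.441). Of the cohesins, Smc3 rose (0.325), Smc1b fell (-0.339) and Smc1a did not pass (-0.0551). Rab GTPases rose in 15 of 50 and fell in 8 (exact test for higher calls, adjusted p = 0.0383), with a median near 0 that changed sign with the scaling. Each of the other 4 kept the sign of its median under the quantile, median and spike scalings; for Zfp genes spike scaling left -0.06, below an all-gene median of 0.11, with 38 lower and 10 higher. Genes are not independent replicates, so these p-values describe clustering of calls in these arrays.

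Of the tests below, only the correlation among myeloid markers and the counts over other splits of the arrays were set before their results were seen; the other tests were chosen after. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4078 genes past the threshold, and was the 1 split of the 10 with as many; the highest of the other splits gave 0. It gave 16 lists, again 1 of the 10 with as many, but other splits gave up to 12 lists at camera's preset correlation. Every other split mixes arrays of both groups, so the group difference widens its spread and enters its contrast. The counts of the other splits are thus not a rate expected by chance.

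Foxp3 fell 63.1-fold while 27 of the other 32 Treg signature genes stayed within 2-fold. T cells other than Treg in place of Treg would lower the whole signature, which was fixed beforehand, but its members without Foxp3 had a median of -0.10 and an SD of 0.708. The median thus lay above a 2-fold fall by more than that SD, although 4 members fell by 2-fold or more. X-linked genes as a set differed from autosomal genes by only -0.00954 (interval over resampled genes -0.0439 to 0.0162). X inactivation would keep this near 0 between the sexes, so it cannot decide whether sex plays a part at Foxp3. A difference between the groups' Foxp3 alleles at the end of the gene is a candidate explanation. The overlapping Ccdc22, with a single probe set, changed by -3.06. The 10 nearest other measured genes had a median of -0.304 and ran from -0.672 to 0.62. Of these, Gripap1, Ppp1r3f, Syp, Wdr45 and 2010204K13Rik passed the threshold lower and Plp2 higher. As Ccdc22 and Foxp3 overlap, less Foxp3 transcript could also lower the Ccdc22 signal, so its fall does not favour an allele difference. The labels give both groups Foxp3cre although the control titles read B6_WT, probe positions were not analysed here, and an effect of Usp7 loss on Foxp3 stays open, untested.

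Targets of p53 rose together with cell cycle genes. The rises did not depend on the choice among 4 scalings. The mitotic median was at least 2.65 under each, with a lowest bootstrap bound, over resampled genes, of 2.11. These scalings kept the median of all genes between -0.0514 and 0.108, too narrow a range to remove such a rise. They therefore cannot decide whether a larger scaling error played a part. The p53 target median was 0.628 to 0.837, with a lowest bound of 0.0818 and camera adjusted p of 5.77e-07 or less, while spike scaling took the genes called lower from 1976 to 944. In a form run first, the p53 excess over all genes was at least 0.652, but its bootstrap bound of 0.15 lay under the 0.3 set for that form. Sex cannot be told apart from group: 0 USP7-titled arrays and 3 control arrays had Xist above Eif2s3y. Loss of Usp7, the difference the titles name, also stays open.

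Myeloid markers rose although the cells were sorted as CD4+YFP+. If phagocytes varied between arrays, the 18 markers that rose would vary together within groups; their mean correlation was 0.00917, at the 62.6th percentile of 1000 random lists matched on expression, which decides nothing. A lower share of T cells would raise other cell types alike. The myeloid median of 0.762 exceeded those of 6 other marker lists, without shared genes, by 0.463 to 0.959. This was tested in 3 forms. With B cell, CD8 T and NK, and dendritic markers alone, adjusted permutation p was 0.0681 to 0.111 for genes above the median gene and 0.0711 to 0.185 for all members. With plasma cell, erythroid and stromal markers added, the CD8 T and NK excess of 0.89 reached 0.0474, though that list went both ways. Erythroid and stromal excesses, 0.959 and 0.826, reached 0.036 and 0.009, but 1 of 14 and 3 of 18 of their members lay above the median gene in controls, too dim to decide. As the outcome depends on the form, a lower share of T cells stays open. The abundant Ctss fell while Ifitm3 rose, and myeloid cells in the sort, expression of these genes by Treg and sex all stay open.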
